A study of Homo sapiens with 12 samples.

How the data were processed

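Bulk RNA sequencing was analysed for 12 libraries of HLE-B3, an established line of human lens epithelial cells immortalised with SV40 large T antigen. The titles and descriptions place the libraries in 4 groups of 3. Control libraries 1 to 3 and libraries 1 to 3 labelled GAS5 knockout form set 1, and control libraries 4 to 6 and libraries 4 to 6 labelled GAS5 knockout form set 2. The division into 2 sets follows the labels, where the biosample numbers restart at library 4 and the second controls carry a differently worded description. What separates the sets and how GAS5 was knocked out are not given in the sources used here. The labels do not say whether the libraries of a group came from separate cultures, so every p-value measures only the spread between these samples.

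Per the labels' protocols, RNA was extracted with TRIzol, poly(A)-selected, made into strand-specific libraries by the dUTP method and sequenced as read pairs on an Illumina instrument. The deposited count table gives whole-number read counts per gene symbol, per the file headers, with no normalization. The deposited FPKM table gives the authors' FPKM, fragments scaled by gene length and library total, for the same genes and libraries, per the file headers. The genome build is hg38, per the labels. The aligner, the counting tool, the annotation release and the use of strand in counting are not given in the sources used here. Reads of near-identical copies, such as ribosomal protein genes and their pseudogenes, and reads of genes that overlap on the other strand may therefore be divided between genes in an unknown way.

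The tables hold 23259 genes. In 10868 genes with at least 10 counts in every library, the FPKM equalled the count divided by 1 length per gene and 1 factor per library within 0.1% in 99.96% of genes, and the zeros were the same in both tables. The FPKM were therefore used only as an alternative unit. Total counts ranged from 16000797 to 32729958 per library. Comparing each pair of libraries by the scatter of counts beyond counting error showed no duplicated library, the lowest ratio of chi-squared to its degrees of freedom being 6.51 within the first controls and 10.7 between libraries of different groups.

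Gene counts were compared with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 13488 genes, and libraries were scaled by TMM. A single quasi-likelihood (QL) model of the 4 groups was fitted to all 12 libraries, with 8 residual degrees of freedom and a common biological coefficient of variation of 0.229. Genes were called at a Benjamini-Hochberg (BH) adjusted p under 0.05, two-sided. The contrasts were the libraries labelled knockout minus controls in set 1, the same in set 2, the mean of both, the difference of the second from the first, and the second controls minus the first. The second libraries labelled knockout minus the first were added after the data were seen. Expression is given as TMM-normalised CPM (counts scaled to a common library total), as mean ± SD over 3 libraries, and errors of log2 fold changes are standard errors (SE) of the edgeR fit.

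The model, the contrasts, 33 gene lists, the rule for the genes named and the alternatives were chosen before the data were examined, except those marked here as added later. The lists were the GAS5 neighbourhood on chromosome 1q25, snoRNA host genes, cytosolic ribosomal proteins, senescence-associated secretory factors, senescence and ageing regulators, p53 targets, S-phase genes, G2/M-phase genes, glucocorticoid receptor targets, miR-21 targets, lens epithelial genes, crystallins and lens fibre genes, epithelial-mesenchymal transition and matrix genes, YAP/TAZ targets, NRF2 antioxidant genes, other antioxidant enzymes, integrated stress response genes, endoplasmic reticulum chaperones, heat-shock genes, interferon-stimulated genes, NF-kappa-B targets, cholesterol synthesis genes, hypoxia and glycolysis genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, apoptosis regulators, autophagy and lysosome genes, replication-dependent histone genes, and markers of keratinocytes, retinal pigment epithelium, endothelial cells, leukocytes and fibroblasts. Lists with at least 5 tested members, 32 in all, were tested with camera (limma 3.58.1) on voom values with a preset correlation between genes of 0.01, and p was BH-adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it.

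The genes named are GAS5; per comparison the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in which every library labelled knockout lay beyond every control of its set; per list described up to 2 called members with the largest rise and 2 with the largest fall at that level, or else the 2 with the highest CPM; and for the difference between sets the 5 highest and 5 lowest. Readthrough, antisense, unnamed, Y-linked and X-inactivation genes were left out of the rankings, and 3 other genes that meet these rules are not reported here.

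The alternatives were DESeq2 size factors, no low-count filter, a minimum mean of 5 CPM, the DESeq2 1.42.0 Wald test, each set fitted alone, the library number as a replicate block, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1 and a minimum mean FPKM of 1, the same with a pseudocount of 1 and no filter, each library left out in turn, a minimum log2 fold change of 1, and 6 controls against 6 libraries labelled knockout with no set term. Added after the data were seen were the removal of trends with GC content and gene length (natural splines with 5 degrees of freedom per library, entered as offsets), the omission of libraries 2 and 6 labelled knockout, and a restriction to 2238 genes of 48 to 53% GC. GC content was the median over a gene's GENCODE 29 transcripts and was found for 95.0% of tested genes, and length was derived from the ratio of counts to FPKM. A test of the pathway names in the deposited gene annotation was also added.

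The fits were tested on simulated counts with the real library sizes and the same mean per gene in all groups. For each comparison below 200 genes of at least 5 CPM were changed. Data in which most genes differ, as in set 2 and between the controls, were not simulated. In set 1, 8.96% of genes changed 1.5-fold, 55.2% of genes changed 2-fold and 90.9% of genes changed 4-fold were recovered, and in set 2 4.48%, 53.7% and 95.5%. For the difference between sets the shares were 0%, 8.96% and 87.9%, and for the second libraries labelled knockout against the first 7.46%, 52.2% and 93.9%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.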

Results

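Gene expression was measured by RNA sequencing in 12 libraries of the lens epithelial line HLE-B3, and the study asks what GAS5, a long non-coding RNA that hosts small nucleolar RNAs, does in these cells. Set 1 holds 3 control libraries and 3 libraries labelled GAS5 knockout, and set 2 holds another 3 of each. Total counts per library ranged from 16000797 to 32729958, and 13488 genes were tested with edgeR.

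On TMM-scaled counts, GAS5 was not lower in the libraries labelled knockout. In set 1 it stood at 3.94 ± 0.26 CPM (library-scaled counts; mean ± SD, n = 3) in controls and at 6.27 ± 0.17 CPM in the libraries labelled knockout, with 6.44, 6.28 and 6.10 CPM in the latter against 4.13, 4.05 and 3.64 CPM. The log2 fold change was 0.67 ± 0.19 (SE; edgeR QL, BH-adjusted p = 0.0188). In set 2 the means were 3.95 ± 0.87 CPM in controls (4.95, 3.47 and 3.42 CPM) and 5.22 ± 1.01 CPM in the libraries labelled knockout (4.61, 4.66 and 6.38 CPM), a log2 fold change of 0.40 ± 0.19 that did not pass the test (edgeR QL, BH-adjusted p = 0.0732). Raw GAS5 counts lay between 65 and 194 per library. The set 1 call was lost when control library 2, control library 3 or library 2 labelled knockout was left out (log2 fold change 0.69, 0.62 and 0.65). It was also lost with the replicate number as a block (0.67, BH-adjusted p = 0.056) and by limma-trend on FPKM without a filter (0.31, BH-adjusted p = 0.059), where the set 2 rise passed the test (0.27, BH-adjusted p = 0.048). In set 2 the rise passed the test without control library 4 (0.65) and stood at 0.24 without library 6 labelled knockout. It turned to -1.38, a fall that passed the test (edgeR QL, BH-adjusted p = 0.0011), when trends with GC content and length were removed. The count table is keyed by symbol; in the GENCODE annotation of GRCh38, GAS5 (ENSG00000234741.7) lies on the minus strand of chromosome 1 from 173863900 to 173868882 and overlaps GAS5-AS1 and ZBTB37 on the plus strand. Its FPKM imply a length of 4980 bp, close to the whole span of 4983 bp. Which parts of the locus gave the reads is not known. GAS5 was low in every library, controls included, at 0.58 to 1.32 FPKM. Its rise in set 1 is a shift between low levels and does not show whether the knockout labels are right. Since GAS5 on TMM-scaled counts goes against the labels, every direction below refers to the labels alone.

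**Figure D1:**
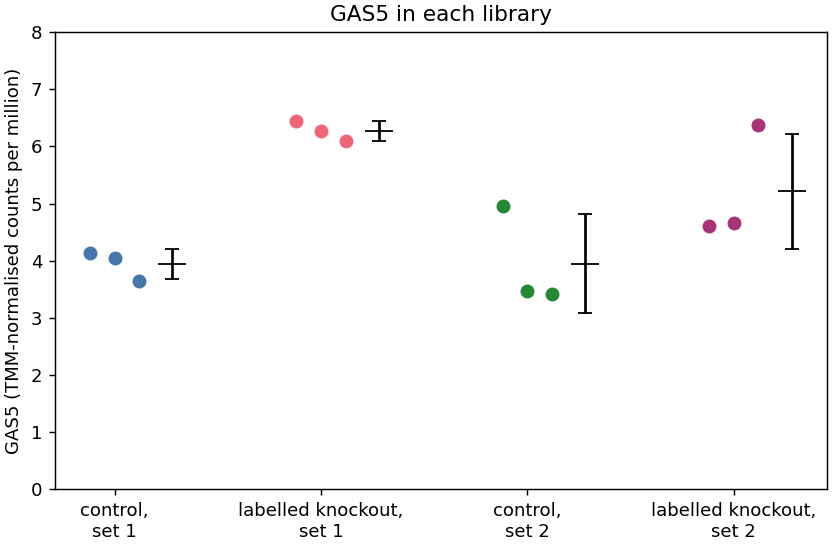
GAS5 in TMM-normalised CPM (vertical axis) in each library (points) of the 4 groups, with the mean and SD of 3 libraries as bars. The libraries labelled knockout in set 1 sit between 6.10 and 6.44, above the controls of set 1 at 3.64 to 4.13.

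In set 1, the libraries labelled knockout had lower levels of most S-phase, G2/M-phase and cholesterol synthesis genes, and higher levels of most ribosomal protein and integrated stress response genes. With an estimated correlation the S-phase call held (adjusted p = 0.00029) and the other 4 did not (adjusted p = 0.16, 0.10, 0.38 and 0.16). MKI67, the proliferation marker, fell by 4.85 ± 0.66 on the log2 scale, from 120.1 ± 5.54 to 4.19 ± 2.88 CPM (28.9-fold lower). TNC, the matrix protein tenascin-C, rose 20.0-fold, from 36.0 ± 5.34 to 720.2 ± 42.2 CPM. ACAT2, which makes acetoacetyl-CoA, a first step towards cholesterol, fell by 2.44 ± 0.16 on the log2 scale. The stress-induced gene CHAC1 was 7.32-fold higher at 63.3 ± 10.9 CPM against 8.67 ± 1.02 CPM.

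The edgeR test called 4647 genes in set 1, 2655 higher and 1992 lower in the libraries labelled knockout, of which 1917 changed at least 2-fold. In 54.6% of genes the 2 groups did not overlap, where chance gives 10%. The largest rises were in INHBE, LCN2, PTPDC1, TNC, ANKRD30BL, IL20RB, FOSB, FOS, IL11 and IL1A, with log2 fold changes from 4.98 ± 0.18 for INHBE (BH-adjusted p = 6.2e-08) to 3.12 ± 0.27 for IL1A (BH-adjusted p = 1.4e-05). They include the immediate early transcription factors FOS (3.03 ± 0.51 to 29.5 ± 11.5 CPM) and FOSB (3.97 ± 0.56 to 43.4 ± 7.65 CPM), and the cytokines IL11 (1.94 ± 0.29 to 18.3 ± 2.52 CPM) and IL1A (9.47 ± 1.98 to 82.5 ± 13.9 CPM). LCN2, the siderophore-binding protein lipocalin-2, went from 5.02 ± 0.46 to 136.9 ± 2.37 CPM. The largest falls were in ASPM, MKI67, CDCA3, KIF20A, KIF15, CENPE, MNS1, KNL1, SGO2 and PRR11, with log2 fold changes from -4.93 ± 0.94 for ASPM (BH-adjusted p = 0.00217) to -3.96 ± 0.33 for PRR11 (BH-adjusted p = 9.6e-06). ASPM acts at spindle poles, KIF20A, KIF15 and CENPE are mitotic motor proteins, and KNL1 and SGO2 act at kinetochores and centromeres.

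Of 46 tested S-phase genes, 45 fell and 1 rose (45 and 1 adjusted over the list alone), with a median log2 fold change of -1.68 (camera, BH-adjusted p = 2.1e-26). This was the only list of set 1 whose call held with an estimated correlation (adjusted p = 0.00029). EXO1, a DNA exonuclease, fell from 26.4 ± 4.57 to 2.48 ± 0.86 CPM, and CLSPN, the checkpoint protein claspin, from 38.7 ± 4.07 to 3.72 ± 1.28 CPM. The exception was UNG, a uracil-DNA glycosylase, at 12.3 ± 0.39 and 20.3 ± 1.92 CPM. Of 44 G2/M-phase genes, 43 fell and 0 rose (44 and 0 adjusted over the list alone), with a median of -2.75 (camera, BH-adjusted p = 8.4e-25; adjusted p = 0.16 with an estimated correlation). Across the 6 libraries labelled knockout in both sets, the G2/M median ranged from -3.59 to -2.55 against the first controls.

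**Figure D2:**
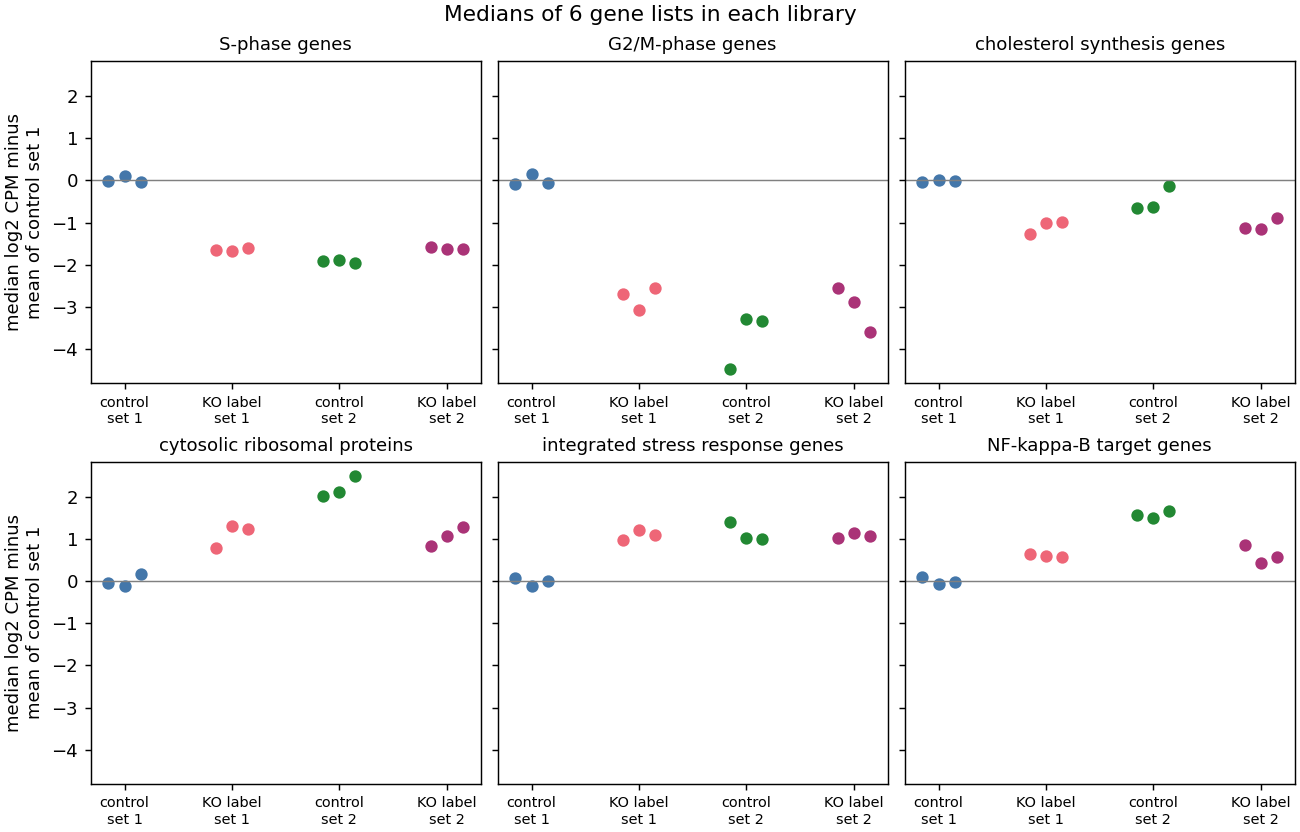
Median over 6 gene lists of log2 CPM minus the mean of the first controls (vertical axis) in each library (points) of the 4 groups. The S-phase median lies between -1.95 and -1.59 in the libraries labelled knockout and in the second controls, and the ribosomal protein median of the second controls, 2.02 to 2.48, is above those of the libraries labelled knockout, 0.78 to 1.30.

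Of 22 cholesterol synthesis genes, 18 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -1.08 (camera, BH-adjusted p = 4.9e-09; adjusted p = 0.10 with an estimated correlation). The list includes ACAT2, and its 1 higher member was TM7SF2, a sterol reductase, at 22.3 ± 1.79 and 35.7 ± 6.01 CPM. Of 31 integrated stress response genes, 24 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 1.07 (camera, BH-adjusted p = 5.3e-11; adjusted p = 0.16 with an estimated correlation). DDIT4, an inhibitor of mTORC1, rose from 11.5 ± 1.26 to 62.3 ± 13.3 CPM. Of 22 endoplasmic reticulum chaperone genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.26; camera, BH-adjusted p = 0.014; adjusted p = 0.61 with an estimated correlation). HSPA5, the chaperone BiP, rose from 1676 ± 129 to 4475 ± 174 CPM and HERPUD1 from 93.0 ± 5.34 to 297.9 ± 29.2 CPM, and SDF2L1 fell by 0.73 ± 0.24, a call lost (values from -0.78 to -0.56) without control library 1, 2 or 3 or library 1 or 2 labelled knockout of set 1, or library 5 of either group of set 2.

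Of 74 cytosolic ribosomal protein genes, 63 rose and 0 fell (66 and 0 adjusted over the list alone), with a median of 1.12 (camera, BH-adjusted p = 1.4e-18; adjusted p = 0.38 with an estimated correlation). RPL12 rose from 57.6 ± 13.4 to 208 ± 55.5 CPM. Among called members with a mean of at least 5 CPM, RPS26 had the largest value, 2.79 ± 0.88. Many pseudogenes share its sequence and 1 library decides it: without library 3 labelled knockout its log2 fold change was 0.36. RPS18 rose more, 97.1-fold from 0.192 ± 0.238 to 17.6 ± 16.5 CPM, but was not among the called members. Ribosomal protein genes took 3.89 to 4.65% of counts in the first controls and 6.72 to 9.73% in the libraries labelled knockout of set 1. Of 56 nuclear oxidative phosphorylation genes, 14 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.32; camera, BH-adjusted p = 0.043; adjusted p = 0.80 with an estimated correlation), with CYC1, cytochrome c1, at 1.17 ± 0.18 and SDHA, a succinate dehydrogenase subunit, at -0.71 ± 0.15. Of 10 mitochondrially encoded genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone; median -2.60; camera, BH-adjusted p = 0.0011; adjusted p = 0.44 with an estimated correlation), but these transcripts were scarce, MT-ND4 lying at 2.22 ± 1.34 and 0.396 ± 0.093 CPM and MT-ND5 at 1.92 ± 1.31 and 0.254 ± 0.097 CPM.

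Among 32 senescence-associated secretory factors, 17 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.69 (camera, BH-adjusted p = 5.2e-05; adjusted p = 0.16 with an estimated correlation). Besides IL11 and IL1A with log2 fold changes of 3.23 and 3.12, INHBA, the activin A subunit, changed by -1.67 ± 0.30 and SPP1, osteopontin, by -1.27 ± 0.36, the latter not called without control library 2 or library 2 or 3 labelled knockout. Of 21 NF-kappa-B targets, 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.57; camera, BH-adjusted p = 0.0011; adjusted p = 0.16 with an estimated correlation). CXCL8, the chemokine interleukin-8, rose from 169.9 ± 16.3 to 1014 ± 201 CPM, and TRAF1 from 3.79 ± 0.92 to 13.9 ± 3.51 CPM. Of 16 glucocorticoid receptor targets, 9 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.87; camera, BH-adjusted p = 0.00034; adjusted p = 0.15 with an estimated correlation). LCN2 and ERRFI1, an inhibitor of EGF receptor signalling (521 ± 13.7 to 1854 ± 97.9 CPM), were among them, whereas FKBP5, a widely used readout of the receptor, was lower at 71.5 ± 7.82 against 114 ± 11.7 CPM, a call lost with GC and length trends removed (-0.34).

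Of 30 hypoxia and glycolysis genes, 12 rose and 4 fell (15 and 4 adjusted over the list alone; median 0.39; camera, BH-adjusted p = 0.014; adjusted p = 0.44 with an estimated correlation). NDRG1, induced by hypoxia, rose by 2.84 ± 0.15 on the log2 scale, DDIT4 by 2.44 ± 0.20, and PKM, pyruvate kinase, changed by -0.63 ± 0.11. Of 31 interferon-stimulated genes, 12 fell and 4 rose (14 and 4 adjusted over the list alone; median -0.92; camera, BH-adjusted p = 0.0082; adjusted p = 0.62 with an estimated correlation). IFIT1 went from 38.6 ± 10.6 to 11.5 ± 2.04 CPM and IFI44 from 8.73 ± 3.68 to 2.28 ± 0.81 CPM, while ISG20 and PLSCR1 had log2 fold changes of 0.89 ± 0.19 and 0.60 ± 0.12.

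The senescence and ageing regulators went both ways, 5 rising and 13 falling of 42 (6 and 14 adjusted over the list alone; camera, BH-adjusted p = 0.070). TXNIP, which binds thioredoxin, rose by 2.31 ± 0.26 on the log2 scale, and CDKN2B, the cell cycle inhibitor p15, rose from 33.7 ± 2.10 to 95.4 ± 4.55 CPM. LMNB1, lamin B1, fell from 304 ± 30.9 to 60.8 ± 0.25 CPM, and CDKN2C, the inhibitor p18, from 126.7 ± 10.2 to 30.4 ± 6.65 CPM. Of 27 p53 targets, 10 rose and 4 fell (10 and 5 adjusted over the list alone; camera, BH-adjusted p = 0.26), with BBC3 and EDA2R at log2 fold changes of 1.67 ± 0.20 and 1.52 ± 0.23 and the DNA repair genes DDB2 and POLH at -1.12 ± 0.21 and -0.86 ± 0.18. Lens epithelial genes were divided, 5 rising and 4 falling of 16 (5 and 4 adjusted over the list alone). FGFR1 and ROR2 rose by 0.63 ± 0.10 and 0.75 ± 0.15, and EYA1 and the transcription factor gene TFAP2A changed by -1.70 ± 0.41 and -1.13 ± 0.14.

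Other lists did not pass camera in set 1, with adjusted p from 0.089 to 0.88. Higher and lower members (in brackets adjusted over the list alone) were 13 and 8 of 41 epithelial-mesenchymal transition and matrix genes (13 and 9), where FAP, a fibroblast protease, was lower at -2.10 ± 0.65, a call lost without control library 1, 2 or 3 or library 2 or 3 labelled knockout. They were 2 and 2 of 13 crystallins and lens fibre genes (2 and 2), 6 and 6 of 23 YAP/TAZ targets (6 and 6), 5 and 5 of 17 miR-21 targets (5 and 5), and 2 and 1 of 17 snoRNA host genes (2 and 1). In the GAS5 neighbourhood they were 1 and 2 of 10 (2 and 3). They were 4 and 5 of 26 NRF2 antioxidant genes (6 and 6), 4 and 0 of 21 other antioxidant enzymes (4 and 0), 2 and 2 of 18 heat-shock genes (2 and 0), 8 and 5 of 33 apoptosis regulators (9 and 6), 8 and 5 of 34 autophagy and lysosome genes (9 and 6), and 6 and 1 of 18 histone genes (6 and 1). Of the markers of other cell types, 3 and 1 of 5 keratinocyte genes (3 and 1), 2 and 1 of 5 retinal pigment epithelium genes (2 and 2), 1 and 2 of 6 leukocyte genes (1 and 2), and 2 and 1 of 9 fibroblast genes (2 and 2) were called, and the 4 tested endothelial genes were too few for a list test. Median and mean had opposite signs for the YAP/TAZ, NRF2, heat-shock, pigment epithelium and fibroblast lists, and the median of the miR-21 list, 0.10, was opposite to its camera direction.

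Of simulated 2-fold changes, 55.2% were recovered in set 1. On FPKM without a filter, 43.6% of called genes were higher, against 57.1% on counts.

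In set 2, the libraries labelled knockout, in which GAS5 was lower only with trends removed, differed from their controls at most genes, and the differences followed GC content. Genes for ribosomal proteins and oxidative phosphorylation were mostly lower, calls that did not hold with an estimated correlation (adjusted p = 0.74 for both lists), and genes of low GC content were mostly higher. RPL18, a ribosomal protein gene, stood at 2484 ± 597 CPM in the second controls and at 634 ± 163 CPM in the libraries labelled knockout. GPAM, which starts triglyceride synthesis, stood at 0.161 ± 0.098 and 15.6 ± 8.39 CPM.

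The edgeR test called 10443 genes in set 2, 5431 higher and 5012 lower, of which 7348 changed at least 2-fold, and 78.2% of genes did not overlap between the groups, where chance gives 10%. Median log2 fold changes fell from 2.89 in the tenth of genes with the lowest GC content to -1.19 in the tenth with the highest, over 9290 genes. In set 1 these medians were -0.26 and 0.26. The largest rises were in GPAM, USP37, ZNF559, DOP1A, LRRN3, DIS3, PRKD3, LIG4, RGS2 and CWC22, with log2 fold changes from 6.53 ± 0.58 for GPAM (BH-adjusted p = 1.6e-06) to 5.63 ± 0.84 for CWC22 (BH-adjusted p = 7.3e-05). DOP1A was not called on FPKM without a filter. RGS2, a regulator of G protein signalling, went from 0.282 ± 0.130 to 14.2 ± 2.19 CPM, and LIG4, the ligase of DNA end joining, from 0.267 ± 0.190 to 13.5 ± 8.33 CPM. The largest falls were in COX7C, PIF1, G0S2, DACT3, CLSTN3, CDCA3, KIF18B, AZIN2, CA9 and TK1, with log2 fold changes from -4.97 ± 1.11 for COX7C (BH-adjusted p = 0.00140) to -2.43 ± 0.22 for TK1 (BH-adjusted p = 2.0e-06). COX7C stood at 9.92 ± 9.12 CPM and PIF1 at 10.45 ± 7.89 CPM in the second controls, so these falls rest on uneven control libraries. TK1, the thymidine kinase of dividing cells, went from 55.9 ± 17.3 to 10.4 ± 1.66 CPM, and CA9, a carbonic anhydrase induced by hypoxia, from 9.54 ± 3.35 to 1.73 ± 0.70 CPM. With trends removed these 20 genes stayed called, but the rises ranged from 3.01 for PRKD3 to 4.27 for RGS2, and CA9 and TK1 stood at -0.99 and -0.87.

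Of the 74 ribosomal protein genes, 52 fell and 10 rose in set 2 (52 and 10 adjusted over the list alone), with a median of -1.12 and a mean of -0.72 (camera, BH-adjusted p = 3.6e-05; adjusted p = 0.74 with an estimated correlation). The second controls gave 13.3 to 15.6% of their counts to these genes, the libraries labelled knockout of set 2 7.18 to 9.74%. RPL7 rose by 2.72 ± 0.24 on the log2 scale, and RPS2 and RPL18 changed by -2.21 ± 0.47 and -1.97 ± 0.24, with GC and length trends removed RPL7 stood at 1.28 and RPL18 at -0.81, and the RPS2 call was lost (-0.84). RPS18 had a log2 fold change of 5.26 ± 2.10, but pseudogenes share its sequence and library 4 labelled knockout decides it, the value without that library being -2.43. Of 56 oxidative phosphorylation genes, 35 fell and 6 rose (35 and 6 adjusted over the list alone), with a median of -0.70 (camera, BH-adjusted p = 0.012; adjusted p = 0.74 with an estimated correlation). COX8A changed by -1.75 ± 0.28 and the complex I and III subunits NDUFS1 and UQCRC2 by 2.35 ± 0.29 and 2.19 ± 0.28. With trends removed COX8A stood at 0.16 and NDUFS1 at 0.56, neither of which passed the test, and UQCRC2 at 0.72.

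S-phase, G2/M-phase, integrated stress response and cholesterol synthesis genes did not pass camera in set 2. S-phase genes went both ways, 22 rising and 18 falling (22 and 18 adjusted over the list alone), as did G2/M-phase genes, 20 rising and 14 falling (20 and 14), with medians of 0.11 and 0.79; the camera direction of the latter was opposite to its median, and with trends removed the medians turned to -0.01 and -0.33. In set 2, 9 integrated stress response genes rose and 10 fell (9 and 9 adjusted over the list alone), against 17 and 4 with trends removed, and 5 cholesterol synthesis genes rose and 12 fell (5 and 12). In the GAS5 neighbourhood on chromosome 1q25, 9 of 10 genes rose in set 2 and 0 fell (9 and 0 adjusted over the list alone; median 1.90; camera, BH-adjusted p = 0.071), but with trends removed 3 rose and 2 fell at a median of 0.08. With only 200 genes changed, unlike in set 2 itself, simulated changes of 4-fold were recovered in 95.5% of genes and changes of 1.5-fold in 4.48%.

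**Figure D3:**
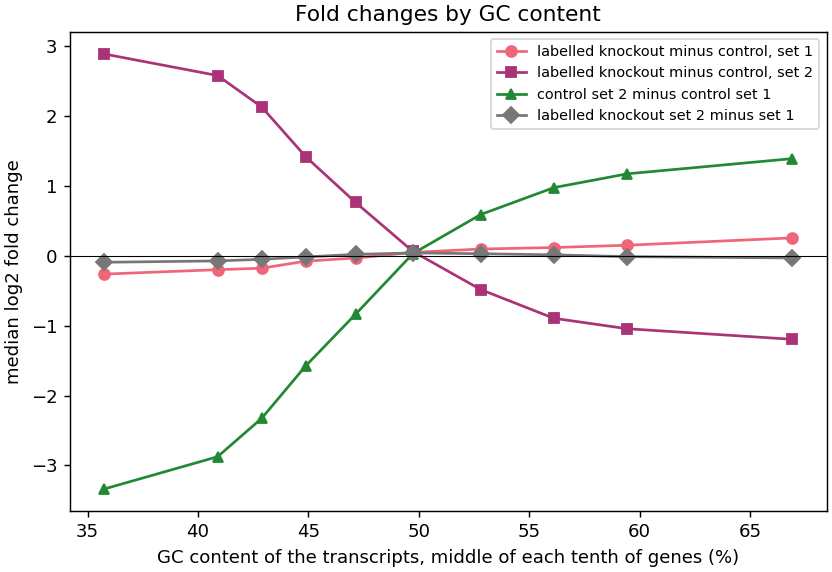
Median log2 fold change (vertical axis) in 10 equal bins of genes ordered by the GC content of their transcripts (horizontal axis, percent) for 4 comparisons (lines). The curves of set 2 and of the second controls against the first run from 2.89 to -1.19 and from -3.34 to 1.39, while the other 2 stay between -0.26 and 0.26.

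The change between controls and libraries labelled knockout differed between the sets, as tested directly, at 9870 genes, 5210 with a higher and 4660 with a lower log2 fold change in set 2. The highest differences were 8.60 for CEP152, 8.41 for DDIAS, 8.16 for KIF14, 8.09 for CENPE and 8.08 for ASPM (SE from 1.23 to 1.69). With trends removed they were 4.84 for ASPM to 6.46 for DDIAS. These genes were nearly absent from the second controls, with 0.0801 ± 0.0509 CPM for CEP152 and 0.822 ± 0.517 CPM for ASPM. Among the lowest differences were -6.77 ± 0.73 for G0S2, an inhibitor of lipolysis, -5.49 ± 0.23 for INHBE, -5.19 ± 0.29 for LCN2 and -5.002 ± 0.42 for SELENOM. BH-adjusted p of these 9 genes ranged from 3.1e-07 to 6.6e-04 (edgeR QL).

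Camera called 10 lists for this difference, and 0 of them held with an estimated correlation, with adjusted p of 0.084 for S-phase genes and 0.53 to 0.58 for the other 9. S-phase genes were 34 higher and 2 lower in set 2 than in set 1 and G2/M-phase genes 34 higher and 1 lower. Ribosomal protein genes were 3 higher and 60 lower. For GAS5 the difference was -0.26 ± 0.27 (edgeR QL, BH-adjusted p = 0.393), and with trends removed it passed the test at -2.27 (BH-adjusted p = 0.00040). With only 200 genes changed, 8.96% of the simulated changes in this difference were recovered at 2-fold and 87.9% at 4-fold.

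Fewer calls than independent lists give went the same way in both sets. The groups labelled knockout differed from each other at 0 genes and the control groups at 11042. The median absolute log2 fold change was 1.41 for the difference between sets, 1.42 between the controls and 0.13 between the groups labelled knockout. The disagreement below therefore follows the control groups and does not tell whether the libraries labelled knockout share a response. Among genes called in both sets, 596 were higher in both, where independent lists give 1069, and 656 were lower in both, where independent lists give 740. Opposite calls numbered 1512 for genes higher in set 1 and lower in set 2, against 987, and 944 for the reverse, against 802. Across the 13488 genes, which are not independent replicates, Pearson's r of the log2 fold changes was -0.31 and Spearman's rho -0.34, and 37.4% of genes had the same sign. In 99 relabellings of the libraries within sets r ranged from -0.58 to 0.58, and 28 lay as far from 0.

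Averaged over both sets, the libraries labelled knockout had lower levels of 24 of 44 G2/M-phase genes, a list call that did not hold with an estimated correlation (adjusted p = 0.82). These genes fell in set 1, whereas in set 2 on TMM-scaled counts they went both ways, with more called higher than lower. The mean GAS5 change of the libraries labelled knockout was 0.54 on the log2 scale (edgeR QL, BH-adjusted p = 0.0049). It was -0.24 with trends removed (edgeR QL, BH-adjusted p = 0.31) and 0.53 without the set term (edgeR QL, BH-adjusted p = 0.058), neither of which passed the test. CDCA3, needed for entry into mitosis, changed by -3.66 ± 0.30, with log2 fold changes of -4.75 ± 0.44 in set 1 and -2.56 ± 0.40 in set 2. IL1A rose by 3.59 ± 0.20, from 9.47 ± 1.98 to 82.5 ± 13.9 CPM and from 4.97 ± 0.53 to 83.3 ± 29.4 CPM.

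The test of this mean called 8143 genes, 4832 higher and 3311 lower. The largest rises were in PTPDC1, ANKRD30BL, IL1A, DMGDH, GTF2H2, FOSB, RGS2, COL14A1, IL20RB and SEL1L, with log2 fold changes from 3.76 ± 0.15 for PTPDC1 (BH-adjusted p = 1.9e-07) to 2.92 ± 0.31 for SEL1L (BH-adjusted p = 1.2e-05). The largest falls were in CDCA3, PIF1, KIF18B, CDCA5, CCNF, ARHGEF39, TROAP, BIRC5, TACC3 and GTSE1, down to -2.43 ± 0.26 for GTSE1 (BH-adjusted p = 1.2e-05). BIRC5, the mitotic protein survivin, stood at 90.4 ± 3.44 and 11.9 ± 3.98 CPM in set 1 and at 52.4 ± 21.2 and 12.7 ± 1.72 CPM in set 2.

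Camera called 4 lists for the mean, of which 0 held with an estimated correlation. None of the 4 passed camera in set 2, so these calls do not show a change of both sets. Of 44 G2/M-phase genes 24 fell and 0 rose (24 and 0 adjusted over the list alone; median -0.87; camera, BH-adjusted p = 2.0e-07; adjusted p = 0.82 with an estimated correlation). Of 46 S-phase genes 26 fell and 7 rose (26 and 7 adjusted over the list alone; median -0.58; camera, BH-adjusted p = 2.1e-06; adjusted p = 0.074 with an estimated correlation), with E2F8 and MCM5 at -2.09 ± 0.20 and -1.81 ± 0.11 and HELLS and MCM6 at 1.42 ± 0.28 and 1.26 ± 0.23. Of 22 cholesterol synthesis genes 16 fell and 3 rose (17 and 3 adjusted over the list alone; median -0.85; camera, BH-adjusted p = 7.0e-05; adjusted p = 0.46 with an estimated correlation), with FDPS at -1.75 ± 0.16 and HMGCS1 at 1.48 ± 0.26. Of 31 integrated stress response genes 22 rose and 2 fell (22 and 2 adjusted over the list alone; median 0.53; camera, BH-adjusted p = 0.0014; adjusted p = 0.88 with an estimated correlation), with CEBPG and SLC7A11 at 1.46 ± 0.09 and 1.37 ± 0.16 and ATF4, the central factor of the response, at -0.35 ± 0.09.

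The rises of HELLS, MCM6 and HMGCS1 rest on their low level in the second controls (3.36, 5.74 and 2.01 CPM) and turn to -0.27, -0.80 and -0.62 without the set term. With trends removed HELLS, MCM6 and HMGCS1 stood at 0.34, 0.49 and 0.53, CEBPG and SLC7A11 at 0.63 and 0.34 and ATF4 at 0.02. GTF2H2, RGS2, SEL1L and SLC7A11 were not called without the set term. Without the set term 1552 genes were called, 38.0% of them higher against 59.3%.

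The second controls differed from the first at 11042 genes, 5453 higher and 5589 lower. ASPM stood at 279 ± 49.8 CPM in the first controls and at 0.822 ± 0.517 CPM in the second, and MKI67 at 120.1 ± 5.54 and 1.41 ± 0.96 CPM. Other cell cycle genes differed far less. TK1 (61.5% GC, against 37.1% for ASPM) stood at 57.5 ± 4.18 and 55.9 ± 17.3 CPM, and BIRC5 (52.3% GC) at 90.4 ± 3.44 and 52.4 ± 21.2 CPM. TNC, LCN2 and INHBE stood at 838 ± 156, 194.5 ± 42.1 and 55.0 ± 7.26 CPM in the second controls, against 36.0 ± 5.34, 5.02 ± 0.46 and 1.13 ± 0.12 CPM in the first. Ribosomal protein genes were 59 higher and 3 lower (59 and 3 adjusted over the list alone; median 2.23, or 1.27 with trends removed; camera, BH-adjusted p = 3.1e-10; adjusted p = 0.63 with an estimated correlation).

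Camera called 10 lists between the controls, and 0 held with an estimated correlation. G2/M-phase genes were 38 lower and 1 higher (38 and 1 adjusted over the list alone; median -3.71, or -2.68 with trends removed; camera, BH-adjusted p = 2.0e-06; adjusted p = 0.63 with an estimated correlation), and S-phase genes 36 lower and 4 higher (36 and 4 adjusted over the list alone; median -1.93, or -1.66 with trends removed; camera, BH-adjusted p = 8.3e-06; adjusted p = 0.098 with an estimated correlation). Senescence-associated secretory factors were 21 higher and 6 lower (21 and 6 adjusted over the list alone; median 1.66, or 1.13 with trends removed; camera, BH-adjusted p = 0.0021; adjusted p = 0.60 with an estimated correlation). Replication-dependent histone genes were 15 higher and 0 lower (15 and 0 adjusted over the list alone; median 1.45; camera, BH-adjusted p = 0.011; adjusted p = 0.63 with an estimated correlation). The median log2 fold change ran from -3.34 in the tenth of genes lowest in GC content to 1.39 in the highest. The 10 most abundant genes took 9.86 to 10.7% of counts in the second controls and 4.73 to 7.17% in the other libraries. A batch of the second controls alone and the group itself cannot be told apart here.

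**Figure D4:**
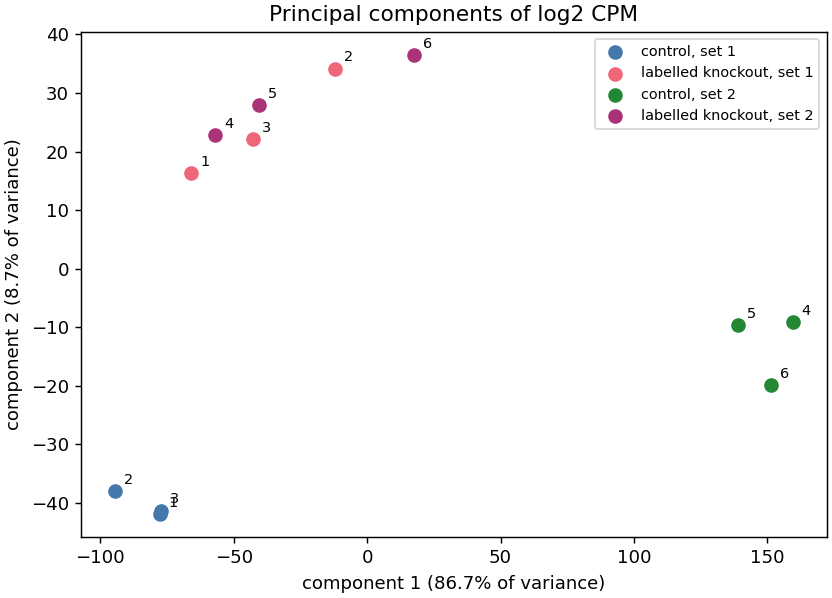
First and second principal components of log2 CPM (axes, 86.7% and 8.69% of the variance) of the 12 libraries, coloured by group and numbered by replicate. The second controls lie apart at 139 to 159 on the first component, the 3 first controls at -94.4 to -77.3, and libraries 2 and 6 labelled knockout are the nearest of their kind to the second controls.

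The 2 groups labelled knockout were alike. MKI67 stood at 4.19 ± 2.88 and 2.19 ± 1.56 CPM, TNC at 720.2 ± 42.2 and 758 ± 54.3 CPM, and CXCL8 at 1014 ± 201 and 1141 ± 214 CPM. The edgeR test called 0 genes between them, with 245 genes at an unadjusted p under 0.05; DESeq2 called 0, and limma-trend called 0 on FPKM with a filter and 2 without. Simulated 2-fold changes were recovered in 52.2% of genes in this comparison and 4-fold changes in 93.9%. The mitochondrially encoded genes were higher in the second group by a median of 2.55 (camera, BH-adjusted p = 7.9e-21; adjusted p = 0.079 with an estimated correlation; 8 higher and 0 lower adjusted over the list alone, 0 over all genes). Glucocorticoid receptor targets and NRF2 antioxidant genes passed camera at medians of 0.14 and 0.10 (BH-adjusted p = 0.040 for both; adjusted p = 0.81 and 0.89 with an estimated correlation), with 0 genes called.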

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

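All 9 tests of an explanation in this part were chosen after the results were seen, as were the regroupings of the genes called in both sets, of the correlation between sets and of the sets labelled knockout; the other regroupings were chosen before. The change between controls and libraries labelled GAS5 knockout differed between the sets at 9870 genes by a direct test of the difference (edgeR QL, BH-adjusted p under 0.05), and that difference is what brings these results here. Since GAS5 on TMM-scaled counts is not lower in the libraries labelled knockout, the directions follow the labels alone.

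The log2 fold change was higher in set 2 by 8.60 for CEP152, 8.41 for DDIAS, 8.16 for KIF14, 8.09 for CENPE and 8.08 for ASPM. The change was lower in set 2 by -6.77 for G0S2, -5.49 for INHBE, -5.19 for LCN2 and -5.002 for SELENOM. Median differences were 3.21 for G2/M-phase genes and 2.04 for S-phase genes. They were -2.24 for cytosolic ribosomal proteins, -1.72 for senescence-associated secretory factors, -1.41 for NF-kappa-B target genes, -1.31 for replication-dependent histone genes, -1.19 for hypoxia and glycolysis genes, -1.14 for integrated stress response genes, -1.03 for nuclear oxidative phosphorylation genes and -1.0 for other antioxidant enzymes. None of these 10 list calls held with an estimated correlation (camera, adjusted p = 0.084 for S-phase genes and 0.53 to 0.58 for the others), and with trends removed the medians were 2.50 and 1.67 for the rises and, in the order given, -1.42, -1.09, -0.95, -1.65, -0.16, -0.48, -0.56 and -1.04 for the falls. Among the 100 regroupings of the libraries within sets, the real one called the most genes (9870, against 7941 in the highest other). This count also rests on set 2, with 6301 to 7941 genes where set 2 was kept as labelled and at most 310 elsewhere. Low counts elsewhere are expected, since mixing the groups of set 2, which differ at 10443 genes, raises the spread. Only 6 other regroupings kept set 2, too few to exclude chance. The lists were not regrouped.

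The second controls differed from the first at 11042 genes. Trends with GC content and length took 56.7% of the variance of these differences, an association that does not show whether they caused them. With the trends removed 9644 genes were still called, which argues against smooth trends of this kind as the whole cause. In the band of 48 to 53% GC 1690 of 2238 genes were called, but the band does not remove the trends. The median difference between the controls was 0.03 at 48.3 to 51.1% GC and 0.59 at 51.2 to 54.5%. Length was not restricted in the band. How many of the 9644 calls come from error of the correction is not known. A batch shared by every library of set 2 is argued against by the libraries labelled knockout, among which 0 genes were called between sets (edgeR QL; 245 at an unadjusted p under 0.05; DESeq2 0, limma-trend on FPKM 0 with a filter and 2 without). A state of low cell cycle gene levels shared with the libraries labelled knockout is argued against as the whole cause. Cell division itself was not measured in these data, and TK1, the thymidine kinase of dividing cells, stood at 57.5 and 55.9 CPM in the first and second controls. Against such a state alone, set 2 still had 7546 calls with trends removed, more than the 5209 of set 1. Such a state may be part of the cause: over those 5209 genes the slope of the set 2 on the set 1 log2 fold changes was -0.13 (-0.19 to -0.08 with 1 library left out), against 0.96 to 1.06 when the differences between the controls were shuffled over genes, but first controls in an unusual state would give this slope too, and a batch of the second controls alone cannot be told apart from their group.

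On TMM-scaled counts GAS5 was not lower in the libraries labelled knockout of either set. A candidate explanation in set 2 is that GC and length trends hide a fall: with trends removed the log2 fold change was -1.38 and passed the test (edgeR QL, BH-adjusted p = 0.0011), but the corrected difference of GAS5 between the controls, 2.12, lay above only 85% of the 200 genes nearest in GC content and length (SD 2.22), so this cannot be told apart from error of the correction. A swap of the labels in set 1 could also give a higher level, with libraries labelled control at 0.629 times those labelled knockout (95% interval 0.463 to 0.855); a partial loss of GAS5 under swapped labels and a true rise cannot be told apart at this width, though a swap in set 1 alone would have to explain why 0 genes differ between the sets labelled knockout. A deletion that leaves part of the locus transcribed was not tested, since the table holds 1 value per gene.

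Libraries 2 and 6 labelled knockout lay closest of their kind to the second controls, at -12.1 and 17.7 on the first component against -65.9 to -40.6. RNA of the second controls mixed into these libraries is argued against as the whole cause. Genes 4 times higher in the second controls would need a share of 3.46% and 6.58%. Genes 4 times lower would need a share of 33.9% and 58.5%, gaps of 30.4 and 51.9 percentage points. The shares come from CPM with trends left in, so a small mixture is not excluded. GC and length trends took 22.1 and 26.5% of the variance of these libraries. With trends removed they still lay 20.6 and 44.4 beyond the nearest of the other 4 (SD 8.57) on the first component. Their distance argues against smooth trends of this kind as the whole cause, though error of the correction is not excluded. Their G2/M-phase medians with trends removed, -2.85 and -3.30, also lay below those of the other 4 (-2.76 to -2.57), but what sets these libraries apart stays open.

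Regrouping the 6 libraries of a set gives 10 splits, too few for a share under 0.05. In set 1 the real split called 4647 genes and the highest other 0, and 13 lists against 12; in set 2 they were 10443 genes against 0, and 2 lists against 8; 8 of the 10 splits of set 2 called as many lists as the real one. Between the control sets the counts were 11042 and 0. Between the sets labelled knockout they were 0 and 388, in all 10 splits as many as the real one; the split with 388 parts libraries 1, 3 and 4 from 2, 5 and 6, which points to a structure of these samples. For the mean of both sets 2 of 100 regroupings called as many genes (8143, highest other 8551). The 6 others that kept set 2 as labelled called 6618 to 8551 genes and the remaining 93 at most 310. Low counts are expected where the groups of set 2 are mixed, so the share of 2 in 100 does not exclude chance. The count rests on set 2 and does not show a change of both sets. Of the regroupings of the mean, 83 of 100 called as many lists (4; highest other 15), so for the lists chance cannot be excluded. For genes called in both sets in one direction 1 of 100 did (1252; highest other 0), but the other splits of either set call 0 genes, so this outcome was fixed and says nothing about chance. For the correlation of log2 fold changes 29 of 100 lay as far from 0 (-0.31; highest other 0.58), so chance cannot be excluded.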

How the results depend on the processing

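The removal of trends, the omission of libraries 2 and 6 labelled knockout and the band of 48 to 53% GC were chosen after the data were seen, the other alternatives before. Among 294 alternative values of the results per comparison, 262 kept direction and side of the threshold, or for counts stayed within 1.5 times, and 32 did not. The correlation between sets counted as kept if its sign held and it moved by less than 0.27, the SD of the relabelled correlations. That is a wide margin beside its value of -0.31. Of 2884 values of named genes 2832 kept both, 46 lost the call and 6 turned.

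In the band of 48 to 53% GC, with 2238 genes tested, calls numbered 993 in set 1, 1422 in set 2, 1074 for the mean, 1437 for the difference, 1690 between controls and 222 for genes called in both sets in one direction. At a log2 fold change of at least 1 in size, 1917 genes were called in set 1 and 3162 for the mean. Without the set term the mean had 1552, and HELLS stood at -0.27, MCM6 at -0.80 and HMGCS1 at -0.62. On FPKM without a filter, 2 genes were called between the sets labelled knockout, and GAS5 stood at 0.31 in set 1, no longer called, and at 0.27 in set 2, now called. FPKM with a filter moved the median of all genes in set 2 from 0.03 to 0.17 (pseudocount 1) and 0.21 (0.1). With trends removed GAS5 was -1.38 in set 2, COX8A 0.16 and ATF4 0.023, and 5 lists were called in set 2 and 8 for the mean. Camera with an estimated correlation called 1 list in set 1, 0 in set 2 and 0 for the mean; fry called 24 in set 2 and 15 for the mean, and DESeq2 size factors gave 4 in set 2. With the replicate number as a block GAS5 was 0.67 in set 1, not called, and set 1 had 3722 genes; same-numbered libraries deviated together with r from -0.38 to 0.0955 and best with their own number in 0 of 6, so the numbers do not pair the libraries.

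With 1 library left out, GAS5 ranged from 0.62 to 0.70 in set 1 (not called without control library 2 or 3 or library 2 labelled knockout) and from 0.24 to 0.65 in set 2 (called without control library 4). Genes called ranged from 3188 to 5530 in set 1, 9831 to 10675 in set 2, 7450 to 8591 for the mean, 9386 to 10209 for the difference, 10609 to 11304 between controls, 0 to 0 between the sets labelled knockout, and 856 to 1366 in both sets, the correlation from -0.39 to -0.22. Lists ranged from 11 to 14 in set 1, 2 to 5 in set 2 (5 without control library 1, and more than 1.5 times the 2 also without control library 2, 3 or 6 or library 4 or 5 labelled knockout) and 4 to 5 for the mean. RPS18 in set 2 was -2.43 without library 4 labelled knockout and 7.18 without control library 4.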

Other observations

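The pathway tests, the comparison of the sets labelled knockout and the removal of trends were chosen after the data were seen. DNA replication and repair stood out when the pathway names of the deposited gene annotation were tested in set 1, where GAS5 was not lower in the libraries labelled knockout. Of 323 pathways 23 were called by camera, 12 lower and 11 higher, and 0 with an estimated correlation. DNA replication had 25 of 35 genes lower and 3 higher (median log2 fold change -1.23; camera, BH-adjusted p = 1.6e-09; adjusted p = 0.14 with an estimated correlation). The Fanconi anemia pathway had 27 of 47 lower and 1 higher (median -1.01; camera, BH-adjusted p = 1.9e-07; adjusted p = 0.28 with an estimated correlation), and mismatch repair 15 of 23 lower and 1 higher (median -0.99; camera, BH-adjusted p = 3.1e-06; adjusted p = 0.14 with an estimated correlation).

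Among pathways that rose, cytokine-cytokine receptor interaction had 37 of 106 genes higher and 3 lower (median 0.43; camera, BH-adjusted p = 0.0029; adjusted p = 0.14 with an estimated correlation). IL11, IL20RB, CXCL8 and IL1A, which encode cytokines or a receptor chain, rose by 3.23, 4.15, 2.58 and 3.12 on the log2 scale in set 1. In set 2 IL1A, IL20RB and CXCL8 rose by 4.06, 1.76 and 0.74, the last turning to -1.18 with trends removed, and IL11 stood at -0.37, not passing the test (edgeR QL, BH-adjusted p = 0.15), and at 1.10 with trends removed.

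With trends removed the S-phase median of set 1 was -1.63 and the G2/M-phase median -2.75, against -1.68 and -2.75 before; with an estimated correlation the S-phase call held and the G2/M-phase call did not (camera, adjusted p = 0.16). MKI67 fell by 4.85 in set 1, and in set 2, whose controls already had 1.41 CPM of it, its log2 fold change of 0.64 did not pass the test (edgeR QL, BH-adjusted p = 0.40). A candidate explanation is that the libraries labelled knockout and the second controls come from cultures that divided little, but the 7546 genes called in set 2 with trends removed argue against this as the whole difference between them. Not every cell cycle gene went with this explanation: TK1 stood at 57.5 and 55.9 CPM in the first and second controls.

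Genes called in both sets in one direction, 596 higher and 656 lower, were fewer than independent lists give, 1069 and 740. They show no common response, but since the control groups differ at 11042 genes they do not exclude one either. Removing trends changed which genes these were: of 596 higher in both, 236 were shared with the 684 called higher with trends removed, and of 656 lower in both, 277 with the 550, where independent lists give 824 and 639. With trends removed GAS5 stood at -1.38 in set 2, so the sets would then part in the direction of GAS5 as well, with 0.89 in set 1.

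MALAT1, an abundant nuclear RNA in most human cells, had 0 to 2 counts per library, and the mitochondrially encoded genes together 1.66 to 18.7 CPM, so reads of both appear to be missing from the count table in large part, and the mitochondrial list rests on few reads. The cause was not tested.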
